A study of Mus musculus with 7 samples.

How the data were processed

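Small RNA libraries were made from mouse hepatocytes obtained by 2-step collagenase perfusion of the liver and low-speed centrifugation, per the labels' protocols. The 7 libraries fall into 2 genotypes, WT (n = 3) and ALAS12-KO (n = 4), and all carry the treatment label TMX, whose meaning the labels do not spell out. The labels do not say that replicates are separate animals, so p-values measure only the spread between these samples, which may be partly technical. Per the labels, control RNAs were added to the total RNA and a 3' linker was ligated before size selection.

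Each library has 1 deposited table of whole-number read counts per mature miRNA name, with no normalisation, as read from the values themselves. The deposited counts cover 1966 mature miRNAs and 5 summary entries for reads given to no miRNA, named as htseq-count names them. Cutadapt, limma, mm10 and hg38 are listed in the submitters' processing notes, with no role or version. The aligner, the counter and the miRNA annotation are not given in the sources used here. The summary entries were left out of library sizes and tests. Reads aligned outside any miRNA made up 50.9% to 73.7% of all counted reads, and reads not aligned 4.54% to 8.00%. The entries for non-unique alignment and for low quality were 0 in all 7 libraries, so how reads that match several miRNAs were handled cannot be read from the counts. miRNAs of nearly the same sequence are therefore uncertain one by one. These include miR-378a-3p with miR-378c, miR-199a-3p with miR-199b-3p, and members of the let-7, miR-29 and miR-30 families. Mir126b lies within Mir126a on the opposite strand, and whether counting used strand is not given, so miR-126b is uncertain too.

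The total miRNA count ran from 7719180 to 21962191 reads, so 1 CPM, the unit of counts scaled to a common library size, stood for 7.72 to 22.0 reads. Reads carry no molecular identifiers in these tables, so precision was taken from the spread between libraries. The counts of any pair of libraries of 1 group differed by more than sampling noise (chi-square per degree of freedom 112 to 1288), so no pair was treated as 1 library deposited in duplicate.

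Differences were computed as ALAS12-KO against WT with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust fit, TMM factors, filterByExpr with a minimum count of 10), with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 450 miRNAs. Values are TMM-scaled CPM, mean ± SD, and log2 fold changes ± SE. Lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01, for the 17 of 18 lists with at least 3 tested members. Camera with an estimated correlation and fry were alternatives. For the 130 hairpins with both arms tested, limma was applied to the log2 ratio of the minor to the major arm with 0.5 added to each. Shares of reads and medians per library were compared with a two-sided exact permutation test of the difference of means over all 35 splits, whose smallest possible p is 0.0286. Other scalings, DESeq2 1.42.0, limma-voom, other filters, a replicate block and leaving out each library were tried as well.

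The tests of the 3 comparisons, the lists, the rule for naming miRNAs and most alternatives were fixed before the data were examined; the alternatives and the tests of explanations chosen later are named as such in the closing section. Named were the 10 most abundant miRNAs, the miRNAs past the threshold or, with fewer than 5 of those, the 10 lowest p-values, and up to 4 of the most abundant tested members of each list. miRNAs outside this rule are said to be chosen after their values were seen. Positions came from GENCODE M21 on GRCm38 (mm10), in which 65 of the 69 named miRNAs had a hairpin gene, read with Python 3.11.15. The added control RNAs were not analysed here, so the comparisons planned on their scale were not made. Levels are therefore relative to all miRNAs in a library, and a change shared by all of them would not show.

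On simulated counts with the means and depths of this comparison, run over 426 miRNAs, the edgeR test called 16 of 61 miRNAs given a 1.5-fold change, 43 of 60 given a 2-fold change and 61 of 63 given a 4-fold change. Of its 123 calls, 3 were unchanged miRNAs. Only 242 of the 426 were left unchanged, and the Benjamini-Hochberg cutoff is laxer with so many true changes than with few. The simulation therefore does not show how many changes of these sizes would be called in these data. Over 17 simulated lists, both of the 2 lists given a 2-fold change were called and 0 others. Each simulated miRNA was drawn independently, so members of a list were not correlated. In the data the estimated correlation was 0.67 for the miR-30 family and 0.74 for the Dlk1-Dio3 cluster. The simulation therefore does not show how often camera calls lists falsely in these data. Over 130 simulated hairpins, 15 of the 20 given a 4-fold change of the minor arm were called, and 2 others.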

Results

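Small RNAs were sequenced from mouse hepatocytes of 2 genotypes to ask how ALAS bears on small RNAs. ALAS is 5-aminolevulinate synthase, the enzyme of the first step of heme synthesis. WT gave 3 libraries with 16024219, 21962191 and 7719180 miRNA reads for replicates 1 to 3. ALAS12-KO gave 4 libraries with 13173025, 10093244, 17091539 and 16383220 miRNA reads for replicates 1 to 4. Counts of mature miRNAs do not measure the Alas1 or Alas2 transcripts, so the genotype labels were not checked by the loss of either.

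The libraries had the makeup of liver in both genotypes. miR-122-5p, the most abundant miRNA of hepatocytes, took 57.9% ± 1.32 (SD, n = 3) of miRNA reads in WT and 57.7% ± 3.58 (SD, n = 4) in ALAS12-KO, with an exact permutation p of 1. The 10 most abundant miRNAs were miR-122-5p, miR-21a-5p, let-7f-5p, miR-16-5p, miR-148a-3p, miR-126a-3p, miR-101b-3p, miR-29a-3p, let-7a-5p and miR-192-5p. Together they took 80.4% ± 0.644 (SD, n = 3) of reads in WT and 81.0% ± 1.65 (SD, n = 4) in ALAS12-KO, with an exact permutation p of 0.571. miRNAs made up 34.1% ± 10.9 (SD, n = 3) of aligned reads in WT and 35.5% ± 7.59 (SD, n = 4) in ALAS12-KO, with an exact permutation p of 0.8.

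The first comparison asked which miRNAs differed in abundance between the genotypes. No single miRNA passed the threshold, and the lowest p-values belonged to miRNAs of several loci, some of them sharing a hairpin or a cluster. miR-34a-5p, a transcriptional target of p53, stood at 1130 ± 236 CPM (SD, n = 3) in WT and 2416 ± 386 CPM (SD, n = 4) in ALAS12-KO. miR-21a-5p, which is abundant in injured and growing tissue, stood at 35967 ± 2395 CPM (SD, n = 3) and 61580 ± 9531 CPM (SD, n = 4). In the other direction, miR-200a-3p, an epithelial miRNA found in bile duct cells, stood at 96.8 ± 28.4 CPM (SD, n = 3) in WT and 39.0 ± 9.98 CPM (SD, n = 4) in ALAS12-KO.

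The 10 miRNAs with the lowest p-values were each separated between the genotypes in all 7 libraries, and none passed the adjusted threshold. The log2 fold change was 1.10 ± 0.19 (SE) for miR-34a-5p and 0.78 ± 0.14 for miR-21a-5p, both with an edgeR adjusted p of 0.103. Mir34a lies on chromosome 4 at 150068454 to 150068555 on the plus strand, outside any host gene in the annotation. Mir21a lies on chromosome 11 at 86584067 to 86584158 on the minus strand, overlapping an exon of Vmp1. The other arm of the miR-34a hairpin, miR-34a-3p, had a log2 fold change of 1.48 ± 0.33 at 0.731 CPM in WT and 2.05 CPM in ALAS12-KO. miR-378a-3p, from an intron of Ppargc1b on chromosome 18 (61397835 to 61397900, minus strand), had a log2 fold change of 0.86 ± 0.19, and miR-378c, of similar sequence, 0.70 ± 0.18. The other arm of the miR-378a hairpin, miR-378a-5p, chosen after its values were seen, rose less. It had 0.38 ± 0.21 (edgeR adjusted p = 0.341), and the groups overlapped. miR-30e-3p, from an intron of Nfyc on chromosome 4 (120772606 to 120772697, minus strand), had 0.72 ± 0.18. miR-126b-5p, whose hairpin overlaps Mir126a on the opposite strand, had 1.77 ± 0.43 at means of 0.266 CPM in WT and 0.964 CPM in ALAS12-KO, from 2 to 18 reads per library.

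The lower miRNAs among the 10 came from 1 cluster on the minus strand of chromosome 4, inside Ttll10 introns, with Mir429 also in an exon of the noncoding Gm13648. Mir200b lies at 156055681 to 156055750, Mir200a at 156054896 to 156054985 and Mir429 at 156053905 to 156053987. Their log2 fold changes were −1.31 ± 0.27 for miR-200a-3p, −1.27 ± 0.27 for miR-429-3p and −1.30 ± 0.29 for miR-200b-3p, with edgeR adjusted p of 0.113, 0.113 and 0.115.

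**Figure D1:**
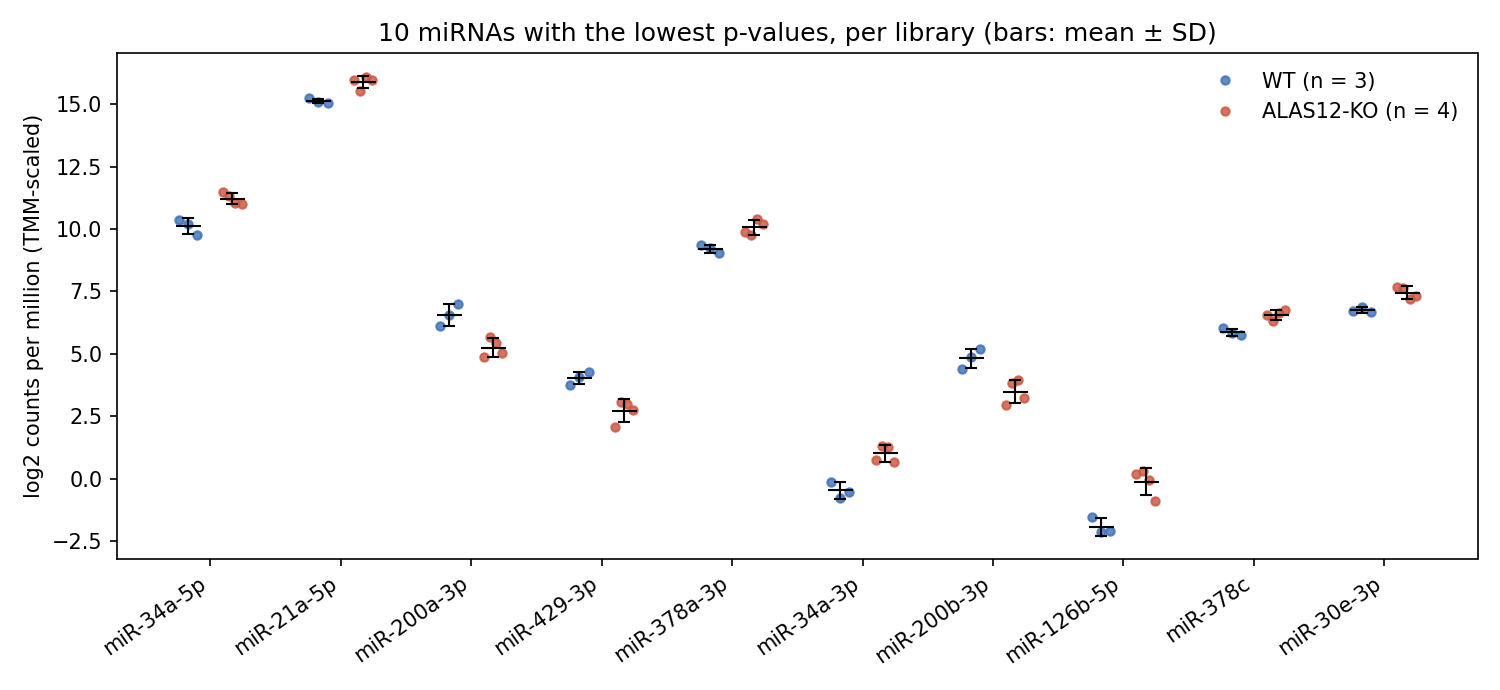
TMM-scaled log2 CPM (counts scaled to a common library size) of the 10 miRNAs with the lowest p-values, 1 point per library (blue, WT, n = 3; red, ALAS12-KO, n = 4), with bars for mean ± SD. miR-34a-5p averages 1130 CPM in WT and 2416 CPM in ALAS12-KO, and each of the 10 is separated between the groups, although none passed the adjusted threshold.

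Among the 10 most abundant miRNAs, miR-21a-5p apart, log2 fold changes ran from −0.61 ± 0.27 for miR-126a-3p, an endothelial miRNA, to 0.39 ± 0.18 for miR-192-5p, and miR-122-5p had 0.20 ± 0.16, a value that changed sign with library totals (−0.0046). The edgeR test called 0 of 450 miRNAs, with 84 at unadjusted p under 0.05 (46 higher, 38 lower), where chance gives 22.5. The groups did not overlap for 91 miRNAs (49 above, 42 below), 20.2% against 5.71% by chance. DESeq2 called 21 (14 higher, 7 lower), among them 9 of the 10 above, limma-voom called 0 with 90 at unadjusted p under 0.05, and limma-voom with sample quality weights, tried after the data were seen, called 4. Scaling by library totals alone called 2, miR-34a-5p and miR-30e-5p, and shifted the median log2 fold change of all tested miRNAs from 0.06 to −0.12. Of the miRNAs at unadjusted p under 0.05, 54.8% were higher with TMM, 27.3% with library totals, 32.9% with upper-quartile factors and 37.0% with the stricter CPM filter.

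The second comparison asked whether groups of miRNAs fixed beforehand stood apart from the rest. The miR-30 family ranked above the other miRNAs, and the imprinted Dlk1-Dio3 cluster on chromosome 12 ranked below them. The miR-30 family took 2.21% ± 0.0196 (SD, n = 3) of miRNA reads in WT and 2.67% ± 0.0274 (SD, n = 4) in ALAS12-KO. The Dlk1-Dio3 cluster took 0.0615% ± 0.0162 (SD, n = 3) and 0.0299% ± 0.00824 (SD, n = 4). Markers of biliary, mesenchymal, leukocyte and red cells and the miR-15/16 family also ranked below the other miRNAs, and hepatocyte miRNAs ranked above them. All 8 of these calls rest on camera's preset correlation, and with an estimated correlation 0 held (adjusted p = 0.531, or 0.565 for leukocytes).

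All 11 tested members of the miR-30 family had a positive log2 fold change, with a camera adjusted p of 6.69e-05. Over all miRNAs 0 of them passed, while 9 passed when adjusted over the list alone. miR-30a-5p had a log2 fold change of 0.42 ± 0.12, miR-30e-5p 0.55 ± 0.15, miR-30c-5p 0.50 ± 0.17 and miR-30d-5p 0.31 ± 0.12. All 41 tested members of the Dlk1-Dio3 cluster were negative, with a median of −0.85 and a camera adjusted p of 3.62e-16. Of these, 18 had an unadjusted p under 0.05, and 0 passed over all miRNAs or adjusted over the list alone. miR-376b-3p had −1.19 ± 0.37, miR-541-5p −0.74 ± 0.28, miR-411-5p −0.73 ± 0.33 and miR-379-5p −0.71 ± 0.31. Without ALAS12-KO replicate 1, these 2 lists were the only ones of the 8 that camera still called. For the Dlk1-Dio3 cluster this library stood against the call. Its mean log2 level over the members, relative to the mean of all libraries, was 0.27, above WT replicate 3 at 0.16. The other ALAS12-KO libraries ran from −0.92 to −0.12, so leaving this library out was no check on that call.

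Of the markers of other cells, 0 passed the adjusted threshold over all miRNAs. ALAS12-KO replicate 1 held the smallest share of several. For cholangiocytes, the cells lining bile ducts, 5 of 6 members were negative (camera adjusted p = 0.0138), and the 3 that passed when adjusted over the list alone were those of the chromosome 4 cluster. miR-141-3p, of another locus, had a log2 fold change of −0.10 ± 0.18. For mesenchymal cells 9 of 10 members were negative (0.00736), with 0 past the list alone and −0.46 ± 0.30 for miR-143-3p and −0.63 ± 0.31 for miR-199a-5p. For leukocytes 10 of 10 were negative (0.0202), with 0 past the list alone, −0.17 ± 0.27 for miR-142a-3p, −0.52 ± 0.29 for miR-146a-5p and −0.41 ± 0.25 for miR-223-3p. For red cells 4 of 4 were negative (0.0326), 2 of them, miR-144-3p (−0.97 ± 0.29) and miR-144-5p (−0.64 ± 0.24), past the list alone, while miR-451a had −0.34 ± 0.31. These 4 were rare, from a mean of 9.38 CPM for miR-451a down to 0.776 CPM for miR-486a-5p. The 2 miR-144 arms share a hairpin, and Mir144 and Mir451a lie side by side on chromosome 11, so the members are not independent. The endothelial list was not called (0.994), and its direction flipped with DESeq2 factors, library totals and upper-quartile factors. Its 4 members were split 2 and 2. The abundant miR-126a-3p and miR-126a-5p were lower, at −0.61 ± 0.27 and −0.51 ± 0.29. The 2 higher members were miR-126b-3p and miR-126b-5p, at means of only 1.73 and 0.665 CPM, whose counts are uncertain. Endothelial miRNAs took 4.20% ± 0.916 (SD, n = 3) of reads in WT and 2.56% ± 1.08 (SD, n = 4) in ALAS12-KO (exact permutation p = 0.0857). They took 1.10% in ALAS12-KO replicate 1 and 2.55% to 3.65% in the other ALAS12-KO libraries. Leukocyte miRNAs took 0.300% in ALAS12-KO replicate 1 against 0.654% to 0.998% in the other ALAS12-KO libraries. Without ALAS12-KO replicate 1 the camera adjusted p was 0.0599 for cholangiocytes, 0.0804 for mesenchymal cells, 0.204 for leukocytes and 0.10 for red cells, and miR-142a-3p had a log2 fold change of 0.03. The leukocyte call was also lost without WT replicate 3 (0.0726) and with library totals (0.0745), and the red cell call without WT replicate 2 (0.104) or ALAS12-KO replicate 3 (0.0946).

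Hepatocyte miRNAs were positive for 11 of 12 members (camera adjusted p = 0.0202), with 0 past the list alone, 0.29 ± 0.16 for miR-148a-3p and 0.35 ± 0.18 for miR-101b-3p. They took 64.6% ± 1.44 (SD, n = 3) of reads in WT and 65.2% ± 3.92 (SD, n = 4) in ALAS12-KO, with an exact permutation p of 0.857. The miR-15/16 family was negative for 11 of 15 members (0.0265; adjusted p = 0.531 with an estimated correlation), with 0 past the list alone. Its most abundant members were close to 0, at −0.12 ± 0.11 for miR-16-5p, −0.07 ± 0.12 for miR-15a-5p and 0.01 ± 0.15 for miR-15b-5p, the last of which changed sign with the scaling. miR-322-5p had −0.54 ± 0.30. Without ALAS12-KO replicate 1 the camera adjusted p was 0.0856 for both lists; the hepatocyte call was also lost without WT replicate 3 (0.0743) or ALAS12-KO replicate 2 (0.0506), and the miR-15/16 call without WT replicate 1 (0.0767). The family took 3.81% ± 0.134 (SD, n = 3) of reads in WT and 3.07% ± 0.203 (SD, n = 4) in ALAS12-KO. Most of this was miR-16-5p, at 3.38% and 2.73%, and shares are on library totals, where its log2 fold change was −0.31 in place of the −0.12 with TMM.

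**Figure D2:**
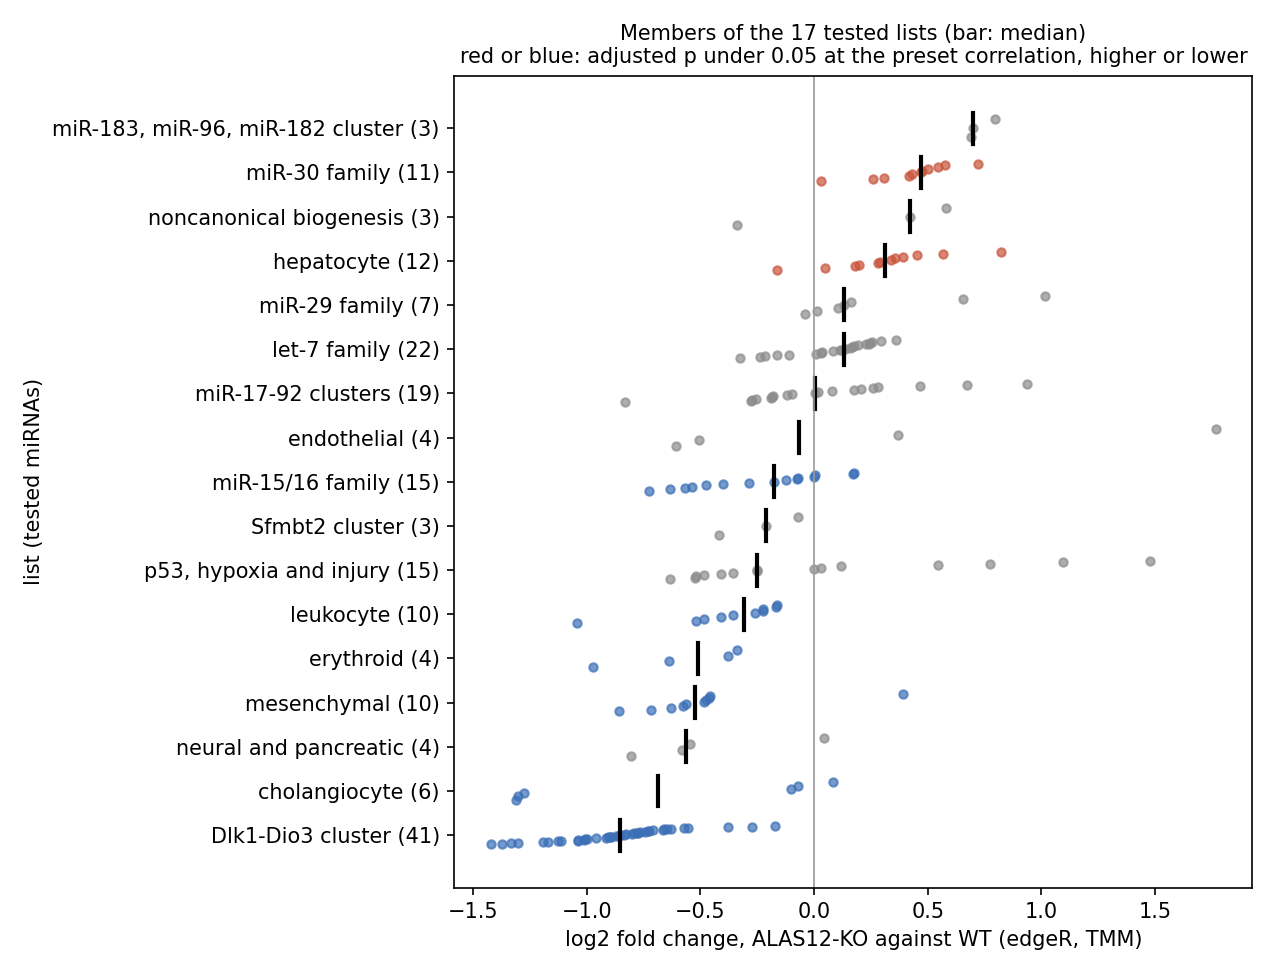
Log2 fold change (ALAS12-KO against WT) of each tested miRNA in the 17 tested lists, 1 point per miRNA, with a bar at each list's median; red and blue mark lists ranked higher or lower at the preset correlation, a call that 0 lists kept with an estimated correlation. All 41 points of the Dlk1-Dio3 cluster lie below 0 and all 11 of the miR-30 family above it. The endothelial points fall on both sides, with the rare miR-126b arms above 0, and that list's direction flipped with the scaling.

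The remaining lists were not called by camera. The cluster of miR-183, miR-96 and miR-182 was positive for 3 of 3 members, with 0.80 ± 0.26 for miR-96-5p, the 1 member past the list alone, and a camera adjusted p of 0.0697. Camera called it without WT replicate 2 (0.0346) or ALAS12-KO replicate 3 (0.00183), with library totals (0.0394) and with upper-quartile factors (0.0461). The list of p53, hypoxia and injury miRNAs, which shares 3 tested miRNAs with the leukocyte list, had members on both sides of 0 (0.874), and its median of −0.25 and mean of 0.04 differed in sign. Its miR-34a-5p, miR-34a-3p and miR-21a-5p passed when adjusted over the list alone, and miR-21a-3p had 0.54 ± 0.22. The miR-29 family (0.165) included miR-29a-3p at 0.13 ± 0.14 and miR-29c-3p at 0.11 ± 0.16, and the let-7 family (0.305) let-7c-5p at 0.14 ± 0.13 and let-7g-5p at 0.25 ± 0.13; miR-29a-3p, miR-29c-3p and let-7c-5p changed sign with library totals. The miR-17-92 clusters (0.845), with miR-19b-3p at −0.25 ± 0.15 and miR-93-5p at 0.18 ± 0.16 (−0.02 with library totals), had a median of 0.01 and a mean of 0.04 where camera ranked the list lower. Neural and pancreatic miRNAs (0.156) took 0.00689% of reads in WT and 0.00607% in ALAS12-KO, and were called without WT replicate 3 (0.0493). Most of these reads were miR-128-3p, at a mean of 60.8 CPM. The next most abundant tested member, miR-129-5p, had 1.54 CPM, so the share rests on 1 miRNA. miRNAs of noncanonical biogenesis (0.502) included miR-320-3p at 0.58 ± 0.20 and miR-484 at 0.42 ± 0.36, and the Sfmbt2 cluster (0.502) miR-669a-3p at −0.21 ± 0.31. Muscle miRNAs had too few tested members for camera and took 7.50e-04% of reads in WT and 4.91e-04% in ALAS12-KO.

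As shares of all miRNA reads, 5 lists reached the smallest exact permutation p of 0.0286, each without overlap between the groups. These were the miR-30 family, the miR-15/16 family, the miR-17-92 clusters, the cholangiocyte markers and the Dlk1-Dio3 cluster. All had a Benjamini-Hochberg p of 0.103 over the 18 lists, so 0 passed. A list at that smallest p could pass over 18 lists only if many more lists reached it as well. The 0 was therefore nearly fixed beforehand. The red cell list and the p53, hypoxia and injury list did not overlap either, each at an exact permutation p of 0.0571. The mean TMM-scaled log2 level over the members of each list, compared by the same exact permutation test, gave other p-values. They were 0.0571 for the miR-30 family, the miR-15/16 family and the cholangiocyte markers, 0.0857 for the Dlk1-Dio3 cluster, where the groups overlapped, and 0.743 for the miR-17-92 clusters. By that measure the miR-29 family alone reached an exact permutation p of 0.0286 (0.220 after Benjamini-Hochberg adjustment), with a difference of 0.29, while its share was 3.73% in WT and 3.51% in ALAS12-KO. Cholangiocyte markers took 0.0185% ± 0.00528 (SD, n = 3) in WT and 0.00814% ± 0.00217 (SD, n = 4) in ALAS12-KO. The list of p53, hypoxia and injury miRNAs took 4.28% ± 0.323 (SD, n = 3) and 6.36% ± 1.62 (SD, n = 4), with an exact permutation p of 0.0571. miR-21a-5p alone made up 3.87% in WT and 5.93% in ALAS12-KO, and the mean log2 level over the 15 members differed by −0.09 (exact permutation p = 0.714).

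**Figure D3:**
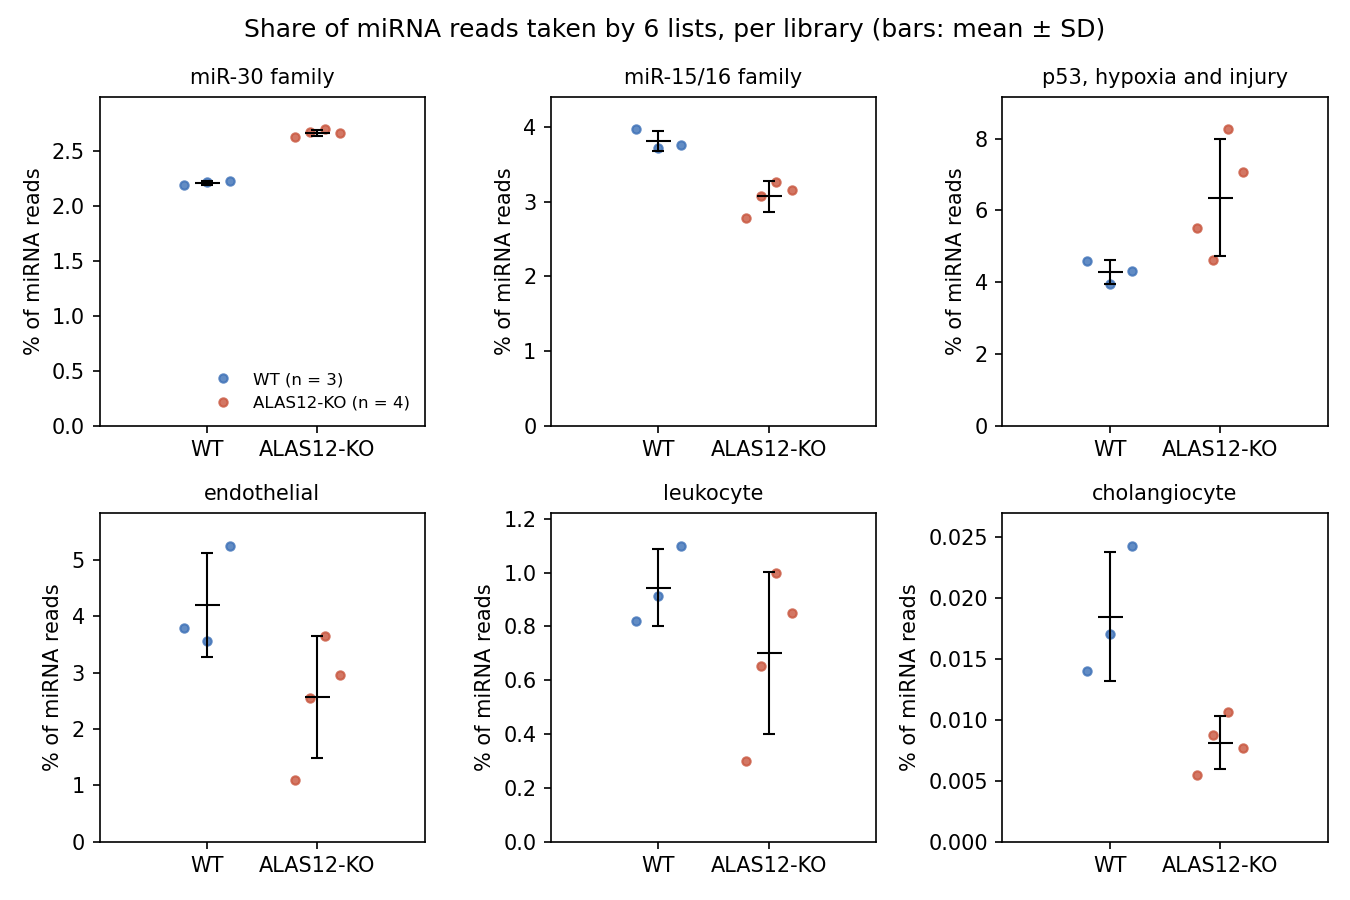
Percent of miRNA reads taken by 6 lists, 1 point per library (blue, WT, n = 3; red, ALAS12-KO, n = 4), with bars for mean ± SD and each axis starting at 0. The miR-30 family takes 2.21% in WT and 2.67% in ALAS12-KO, and the lowest endothelial point, 1.10%, is ALAS12-KO replicate 1.

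The third comparison asked whether the balance of the 2 arms of a hairpin differed, a ratio that does not depend on library scaling. The minor arm stood at a median of 6.01% ± 0.604 (SD, n = 3) of the major arm in WT and 6.19% ± 0.593 (SD, n = 4) in ALAS12-KO, with an exact permutation p of 0.743. On the log2 scale the medians were −4.06 ± 0.14 (SD, n = 3) and −4.02 ± 0.14 (SD, n = 4), with an exact permutation p of 0.714. limma called 0 of 130 hairpins, with 7 at unadjusted p under 0.05 (3 higher, 4 lower) and a lowest adjusted p of 0.345. The small difference of the medians, 0.04, changed sign when 5 was added to each arm (−0.01) and when both arms needed a mean CPM of 10 (−0.22). It also changed sign without WT replicate 3 (−0.01) or ALAS12-KO replicate 1 (−0.06), 3 (−0.06) or 4 (−0.02). The filter was rerun each time a library was left out, so the set of hairpins could change as well.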

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

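The tests of the markers in ALAS12-KO replicate 1 were chosen after its values were seen. In ALAS12-KO (n = 4), 3 of 39 measures had 1 library far from the others, where chance gives about 1.95 (1 in 20). ALAS12-KO replicate 1 was the lowest in each. For miR-126a-3p, the gap to the nearest library was 0.855 of the group's range, above Dixon's critical ratio for 4 libraries. For the mean of the leukocyte markers it was 0.901. For the mean of the muscle miRNAs, with 2 tested members, it was 0.990. That flag rests on the rare miR-1a-3p, at 1.13 CPM in this library. The other member, miR-499-5p, was at its highest of all libraries there, at 0.847 CPM.

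This library was the lowest of the 7 in 16 of the 16 endothelial, leukocyte and mesenchymal markers with a mean CPM of at least 10. These include the markers that drew attention to it, so the count does not decide for fewer such cells, which cannot be told apart from lower levels of the markers within them. The most abundant of the 16, miR-126a-3p, averaged 17457 ± 5539 CPM in ALAS12-KO and 26573 ± 4491 CPM in WT. Shallow sequencing is argued against by its depth, which ranked 3 from the lowest. Low-speed centrifugation is meant to remove such cells, and whether the difference arose in the animal or in the cell preparation was not tested.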

How the results depend on the processing

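Sample quality weights, the marker covariate, other scalings of the list test and all alternatives for shares were chosen after seeing the data. The count of 0 miRNAs became 21 with DESeq2, 13 without a filter (6 higher, 7 lower), 4 with quality weights, 2 with library totals and 1, miR-21a-5p, without ALAS12-KO replicate 2; leaving out any other library gave 0. The 84 miRNAs at unadjusted p under 0.05 became 138 without a filter and 54 with the CPM filter, where 228 were tested, and 45 to 101 when 1 library was left out (45 without WT replicate 2, 49 without WT replicate 1). With the mean of endothelial, leukocyte and mesenchymal markers as a covariate, 0 passed and 94 had an unadjusted p under 0.05. The 8 lists became 0 with an estimated correlation and 0 with fry, and 2 to 8 when 1 library was left out, the 2 without ALAS12-KO replicate 1. Fry's mixed test, of change in either direction, called 2 of the 17 lists, the cholangiocyte markers and the p53, hypoxia and injury list, which is not among the 8 (both adjusted p = 0.0396). The arm difference of 0.04 became −0.0145 with 5 added, −0.22 with the CPM minimum, and −0.0632 to 0.10 with 1 library left out. The miRNA share of aligned reads differed by 1.36 points, and by −4.27 (without WT replicate 3) to 6.62 with 1 library left out. The cause was not tested for any of these beyond the fewer libraries or miRNAs. The share result stayed at 0 lists under all its alternatives. This says little, since with all 7 libraries a pass needed many lists at the smallest exact permutation p. With 1 library left out, the smallest possible exact permutation p is above 0.05, so no list could have passed there. Of 1220 values of named miRNAs, 1129 kept direction and side of the threshold, 29 passed it, 62 changed sign without ever passing, and 0 reversed. Of 221 list values, 178 were the same, 29 lost the call, 6 gained it and 8 changed sign uncalled. Replicate numbers did not pair the samples (correlations 0.14, −0.48 and 0.15, and not every library correlated best with its own number); with a replicate block, 0 miRNAs passed, 60 had an unadjusted p under 0.05, 9 lists were called, the 8 and the cluster of miR-183, miR-96 and miR-182 (adjusted p = 0.0482), and the arm difference was 0.02. The alternatives on the scale of the added control RNAs were not run. Depth limits the rarest miRNAs, such as miR-126b-5p with 2 to 18 reads per library.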

Other observations

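Tests chosen only after the result was seen are those of the split counts of miRNAs and hairpins, of miR-200 against other-cell markers, of library scaling, and of miR-34a-5p, miR-21a-5p and miR-378a-3p against hepatocyte miRNAs.

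Several miRNAs outside the naming rule, chosen after their values were seen, were called by an alternative but not by edgeR with its filter. DESeq2 called miR-22-3p, miR-203-3p and miR-23b-3p, and edgeR without a filter called miR-22-3p, miR-203-3p and miR-150-5p. miR-22-3p stood at 2890 ± 326 CPM (SD, n = 3) in WT and 4184 ± 463 CPM (SD, n = 4) in ALAS12-KO. miR-203-3p stood at 1362 ± 103 CPM (SD, n = 3) and 2106 ± 398 CPM (SD, n = 4). miR-23b-3p had little spread, at 769 ± 24.2 CPM (SD, n = 3) and 990 ± 24.5 CPM (SD, n = 4), a log2 fold change of 0.36 ± 0.11. Their edgeR adjusted p-values were 0.147, 0.156 and 0.195. miR-150-5p, abundant in lymphocytes, stood at 59.8 ± 18.4 CPM (SD, n = 3) and 29.0 ± 12.8 CPM (SD, n = 4), with an edgeR adjusted p of 0.220.

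The 84 miRNAs at unadjusted p under 0.05 were reached by 1 of the 35 splits of the 7 libraries, the real one. The highest other count was 78, with ALAS12-KO replicates 1, 2 and 4 against the rest. A share of 1 in 35 is the smallest this test can give, and the test was chosen after the count was seen. It therefore does not exclude chance. The 0 adjusted calls were matched by 35 of 35 splits (highest other 0), as a count of 0 always is, so this does not bear on chance. The 8 lists were matched by 3 of 35 (highest other 9), so chance was not excluded for the number of lists. The 0 hairpins were matched by 35 of 35 (highest other 1), which again had to be so.

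miR-200a-3p, miR-200b-3p and miR-429-3p were lower together, by −1.30 on the log2 scale in their mean. Relative to endothelial, leukocyte and mesenchymal markers they were still lower by −0.90 (exact permutation p = 0.0286). The mean of those markers itself differed by −0.40 (exact permutation p = 0.257). The 3 were picked for their low p-values in these same libraries, so the test does not decide about a loss of all cells other than hepatocytes. The choice among the 4 scalings tried is argued against as the whole cause, since none moved the median of all tested miRNAs by more than −0.18 from TMM; a shift shared by all miRNAs was not measured. Fewer biliary cells cannot be told apart from lower expression of the cluster, because the difference relative to miR-141-3p and miR-200c-3p, −1.21, had an exact permutation p of 0.0571, short of the bound set beforehand, and whether other cells supply those 2, which differed by −0.10, was not measured. An effect of genotype on the cluster may remain as a hypothesis.

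miR-34a-5p, miR-21a-5p and miR-378a-3p were higher together, with a mean log2 fold change of 0.91. The same bound of −0.18 argues against the choice of scaling as the whole cause. A larger share of hepatocyte RNA would raise the hepatocyte list by about as much. The median over its 12 members was lower, at 0.31 (SD of the members 0.249). The 3 were picked for their low p-values, and the SD of the members is not the spread between libraries, so this comparison does not decide the question. That test was chosen after 2 others had missed 0.05, in which the 3 were higher by 0.62 relative to the list and by 0.73 relative to miR-122-5p, each with an exact permutation p of 0.0571. An effect of genotype may remain as a hypothesis.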
